A study of Mus musculus with 12 samples.

How the data were processed

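RNA was measured by sequencing in 12 samples of sorted mouse intra-aortic cluster cells, 3 for each of 4 combinations of age (E10.5 or E11.5) and cell cycle phase (G1 or S/G2/M). Per the labels' protocols, RNA was isolated from sorted cells, and G1 cells were taken as mKO2-positive and S/G2/M cells as mAG-positive. Per the submitters' processing notes, CASAVA 1.4, TopHat, Cuffdiff and the build mm10 were used, with no role or order given. The labels' protocols instead name bowtie 0.12.2 and the build mm8. Of 22763 gene symbols found in the reference annotation of GRCm38 (mm10), 22438 had a deposited locus that overlapped the reference gene of the same symbol, so coordinates are given as mm10. Deposited starts count from 0, since 11769 equalled the reference start after adding 1 and 676 equalled it as deposited, and they are printed counting from 1. Whether the reads were stranded is not given in the sources used here.

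The authors deposited 6 gene tables with the columns of Cuffdiff's gene test. Each holds 24138 genes and, per the file headers, 1 FPKM value for each of 2 groups, with a p-value and a q-value from the authors' test. The tables name the S/G2/M group with G2, which was read as S/G2/M since no other sorted group exists. No column holds a single sample, so values are printed as the authors' group values without SD. Whether the test used the 3 samples of a group separately is not stated. No read totals are given, and genes of low FPKM did not fall on steps of whole reads, so the depth, and the precision it gives, is unknown. The smallest p-value in the deposited tables is 5e-05. Deposited q-values equalled a Benjamini-Hochberg adjustment over the genes the authors tested. The authors marked genes as significant up to a q-value between 0.0846 and 0.0851 in the table of G1 cells by age, and 0.05 was used here. Genes without enough reads were not tested by the authors, 11147 to 11717 per table, and 7 with too many reads are listed at 0. Of the gene names, 218 join several genes that share reads, 458 occur on more than 1 gene model, and 26 had turned into dates.

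Fold changes were computed here as the ratio of the 2 FPKM values without a pseudocount and equalled the authors' deposited log2 fold changes within 2.78e-05. No fold is given for a gene listed at 0 in a group. No test was run here on single samples, and calls rest on the authors' q-values. For each of 18 gene lists, members called in each direction were counted, q-values were recomputed over the list alone from the authors' p-values, and the median log2 fold change of members above 0 in both groups was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. This percentile describes these libraries and is not a p-value, since genes are not replicates. The lists cover S phase, G2 and mitosis, G1 regulators, complement, stem and progenitor regulators, endothelial genes, erythroid, megakaryocyte, macrophage, granulocyte, lymphoid, germ cell, mesenchymal, and epithelial, hepatic and neural markers, interferon, stress, glycolysis and sex-linked genes. The calculation was tested on simulated data with 40 lists of 20 genes per comparison. There the fold changes were shuffled over the genes and the lists drawn at random. Shuffling removes any shared behaviour of the genes of a real list and any dependence on expression. The simulation therefore checks the calculation and not the shifts of the real lists. For E10.5 phases, over 12845 genes, 1 unshifted list lay outside the central 95% and 38 lists shifted by 0.5 lay above it. For E11.5 phases, over 12315 genes, the numbers were 1 and 37. For age in G1, over 12802 genes, they were 1 and 21, and for age in S/G2/M, over 12596 genes, 4 and 29. All 40 lists shifted by 1 were recovered in each comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

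The groups, the 4 comparisons, the lists, the threshold, the rule for named genes and most alternatives were fixed before the data were examined. The design foresaw count tests for values per sample and, for tables of group values, the calls used here. The rule named, per comparison, the 10 largest rises and 10 largest falls of at least 5 FPKM in the higher group and above 0 in both, at most 2 genes listed at 0 per direction, up to 4 passed members of each list or 2 of the most abundant where none passed, and a fixed set of sort, reporter, complement and cluster genes. Not every gene it selected is printed, and some are withheld and not reported here. Members completing a count of 5 or fewer, such as Top2a at E10.5, Hoxa10, Mllt3 and Myc, were named after their values were seen. The 10 lists and 17 genes plotted were also chosen after the values were seen. The alternatives were thresholds of 0.01 and 0.085, a log2 fold change of at least 1, values of at least 1 or 5 FPKM, a pseudocount of 1, median scaling and, for the phases, the authors' deposited tables in the other order. Leaving out genes listed at 0 was added after the data were seen.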

Results

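RNA was sequenced from cells of the mouse intra-aortic haematopoietic clusters, groups of cells attached to the wall of the embryonic aorta in which blood stem and progenitor cells arise. The cells were sorted from the aorta-gonad-mesonephros region as SSEA-1-negative, CD31-positive and CD117-positive, at the embryonic stages E10.5 or E11.5, named for the days of gestation. Cells in G1 came from Fucci Red animals, which carry the mKO2 reporter, and cells in S, G2 or M phase (S/G2/M) came from Fucci Green animals, which carry mAG. Phase and reporter strain therefore coincided in every comparison of phases. The 12 samples fell into 4 groups of 3, with 1 group for each age and phase. The values analysed were the authors' group values in FPKM, 1 per gene and group, so no spread between samples could be computed, and the depth of the samples is unknown. A gene is said to have risen, fallen or changed where the q-value in the authors' deposited table was under 0.05. The labels do not say whether the 3 samples of a group came from separate litters, and whether the authors' test used the 3 samples separately is not stated, so these q-values reflect at most a spread between samples that may be technical.

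The first comparison set S/G2/M cells against G1 cells at E10.5. Of the fixed lists, 5 of 32 genes for G2 and mitosis rose in S/G2/M cells, and 3 of 20 epithelial, hepatic and neural markers were higher in G1 cells. Plk1, a mitotic kinase on chromosome 7 (122159437 to 122169875, mm10), rose 4.26-fold, from 17.9 FPKM in G1 to 76.1 FPKM in S/G2/M. Sst, which encodes the neuropeptide somatostatin and lies on chromosome 16 (23889581 to 23890844), fell 30.6-fold, from 148 to 4.84 FPKM. By the authors' deposited table, 85 of 12984 tested genes changed, of which 25 rose and 60 fell in S/G2/M.

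Of the 32 tested genes of the list for G2 and mitosis, 5 rose at E10.5 and none fell, with 20 risen when adjusted over the list alone. The 5 were Plk1, Kif11, Cdk1, Ube2c and Top2a. Kif11, a spindle motor, rose 2.72-fold, to 49.0 FPKM in S/G2/M, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 238 and 635 FPKM. The median log2 fold change of the list was 0.98, above all 10000 random lists of the same size and expression. Prc1, a protein of the central spindle that is outside the list, rose 3.67-fold. None of the 31 genes for DNA replication and S phase passed, 5 of them had an unadjusted p under 0.05 in the authors' deposited table, and the list median was 0.28 (percentile 99.97 of the random lists). Pcna, the sliding clamp of replication, had 350.1 FPKM in G1 and 437 FPKM in S/G2/M. Gmnn and Cdt1, named by the rule as reporter genes, did not pass, with Gmnn at 35.4 and 46.3 FPKM and Cdt1 at 32.8 and 36.4 FPKM. The RNA of these mouse genes is no check of the sort, which was made on the mKO2 and mAG reporters. Mki67 had 26.1 and 39.4 FPKM. Among 19 tested G1 regulators and cell cycle inhibitors, Cdkn1c fell 2.23-fold, from 352 to 158 FPKM, and it was the single member that passed, over all genes and adjusted over the list alone.

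Of the 20 tested epithelial, hepatic and neural markers, 3 fell in S/G2/M at E10.5, and 6 fell when adjusted over the list alone. The 3 were the neuronal genes Tubb3 (135 FPKM in G1 and 25.6 FPKM in S/G2/M), Stmn2 (63.6 and 12.2 FPKM) and Elavl3 (14.3 and 3.76 FPKM). The list median was -1.31, below all 10000 random lists. The 10 largest falls among genes of at least 5 FPKM were those of Sst, Cck, Nxph4, Apobec2, Tubb4a, Cadps, Rtn1, Dcx, Ncan and Dcc. Dcx, a microtubule protein of migrating neurons, fell 8.51-fold, from 61.4 to 7.22 FPKM.

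None of the 20 tested macrophage and monocyte markers passed at E10.5, but 19 were lower in S/G2/M and 4 had an unadjusted p under 0.05 in the authors' deposited table, with a median of -0.69, below all random lists. Among 38 endothelial and arterial genes, Gja5, an arterial gap junction gene, fell 3.02-fold, from 29.1 to 9.62 FPKM, and the list median was -0.40 (percentile 0.01). Gja5 was also the single member that passed when adjusted over the list alone. No gene passed among 38 haematopoietic stem and progenitor regulators (median 0.06), 20 erythroid markers (0.40, percentile 99.89), 19 megakaryocyte markers (0.06), 22 complement genes (-0.35) or 26 mesenchymal markers (-0.16). Genes with an unadjusted p under 0.05 in the authors' deposited table numbered 3, 0, 2, 3 and 0 in these lists, in the same order. With q-values adjusted over the list alone, 1 megakaryocyte marker rose and none of the other lists had a call. Runx1, a transcription factor needed for the clusters to form, had 9.85 FPKM in G1 and 10.3 FPKM in S/G2/M. The complement receptor C3ar1 had 15.5 and 7.89 FPKM, C5ar1 had 6.72 and 6.35 FPKM, and Cd93 had 63.1 and 49.6 FPKM.

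No member passed among 5 granulocyte and mast cell markers, 14 lymphoid markers, 8 primordial germ cell markers, 27 interferon and inflammatory genes, 23 stress and immediate early genes, 23 glycolysis genes and 5 sex-linked genes at E10.5. Unadjusted p under 0.05 was listed in the authors' deposited table for 1, 1, 0, 2, 1, 1 and 2 of them. The medians of the granulocyte and stress lists, 1.29 (above all random lists) and -0.25 (percentile 1.25), lay outside the central 95% of random lists. The granulocyte median rests on only 4 members above 0 in both groups. A granulocyte marker and a sex-linked gene, 1 each, rose when adjusted over the list alone. Mpo, the myeloperoxidase gene, had 14.5 FPKM in G1 and 41.6 FPKM in S/G2/M, with a q of 0.0893 in the authors' deposited table. Of the 85 changed genes, 38 were listed at 0 in a group, 9 in G1 and 29 in S/G2/M, such as Cryba1 (11.7 FPKM in G1). Without these genes 47 remained, and with at least 5 FPKM in the higher group 49 remained. The smallest p in the authors' deposited table, 5e-05, was shared by 64 genes and had a q of 0.0101. No gene could therefore pass a threshold of 0.01.

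The second comparison set S/G2/M cells against G1 cells at E11.5. Some mitotic genes and the progenitor gene Hlf rose in S/G2/M cells, whereas 4 macrophage markers, 4 complement genes and 3 globin genes were higher in G1 cells. Hlf, a transcription factor of stem cells on chromosome 11 (90336535 to 90390917), rose 4.93-fold, from 3.47 to 17.1 FPKM. C1qb, a chain of complement component C1q on chromosome 4 (136880145 to 136886177), fell 4.07-fold, from 645 to 158 FPKM. By the authors' deposited table, 87 of 12414 tested genes changed, with 17 risen and 70 fallen in S/G2/M.

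Of the 32 genes for G2 and mitosis, 3 rose at E11.5, and 18 rose when adjusted over the list alone. They were Plk1 (26.8 and 95.8 FPKM), Top2a (58.1 and 143 FPKM) and Ube2c (330.1 and 803 FPKM). The list median was 0.93, above all random lists, and that of 31 S-phase genes was 0.22, at percentile 97.94, with 0 passed and 0 with an unadjusted p under 0.05 in the authors' deposited table. Among 38 stem and progenitor regulators, 2 rose, Hlf among them, with 3 risen when adjusted over the list alone and a list median of 0.40 (percentile 99.99). Of 19 megakaryocyte markers 1 rose, and the median of that list was 0.52 (percentile 99.98). Mpo rose 3.64-fold, from 93.7 to 341 FPKM, while S100a8, another granulocyte marker, was listed at 0 in S/G2/M against 13.1 FPKM in G1. The DNA methyltransferase gene Dnmt3b rose from 14.6 to 61.4 FPKM and the adhesion receptor gene Adgrg1 rose 3.34-fold. The lymphoid marker Cd7 was listed at 0 in G1 and had 2.59 FPKM in S/G2/M. In these lists 1 megakaryocyte, 1 granulocyte and 1 lymphoid marker rose and 1 granulocyte marker fell when adjusted over the list alone.

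Of the 21 tested macrophage and monocyte markers, 4 fell in S/G2/M at E11.5, 14 fell when adjusted over the list alone, and all 21 were lower. The 4 were Cd68 (186 FPKM in G1 and 39.9 FPKM in S/G2/M), Adgre1 (47.1 and 11.6 FPKM), Csf1r (228 and 73.5 FPKM) and Cx3cr1 (112 and 37.2 FPKM). Of the 22 complement genes, 4 fell and 6 fell when adjusted over the list alone. Among them, C1qa fell 6.06-fold, C1qb 4.07-fold and C1qc 3.63-fold. The medians of both lists, -1.31 and -0.92, lay below all random lists, and the lists share 1 gene, Itgam. C3ar1, on chromosome 6 (122847140 to 122856157), had 91.8 FPKM in G1 and 30.9 FPKM in S/G2/M, with a q of 0.0546 in the authors' deposited table. In the authors' deposited table of the same groups in the other order, its values were 92.9 and 30.5 FPKM with a q of 0.0209, so its call depended on the table. C5ar1 had 43.9 and 13.3 FPKM, with a q of 0.0633 in the authors' deposited table, and Cd93 had 142 and 112 FPKM. C3 had 0.439 and 0.473 FPKM and was not tested by the authors.

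Of the 19 tested erythroid markers, 3 fell at E11.5, 7 fell when adjusted over the list alone, and the list median was -1.46, below all random lists. Hba-x fell 4.37-fold, from 7312 to 1674 FPKM, Hba-a2 fell 6.64-fold and Hbb-bh1 3.60-fold, with the caveat that globin genes share sequence. Hmox1, which degrades haem, fell 6.44-fold, from 179 to 27.8 FPKM. Among 38 endothelial genes, Lyve1, a hyaluronan receptor also made by macrophages, fell 10.1-fold, 2 members fell when adjusted over the list alone, and the median was -0.41 (percentile 0.02). Pecam1, which encodes the sort marker CD31, had 111 FPKM in G1 and 69.9 FPKM in S/G2/M, and Kit, which encodes CD117, had 16.9 and 28.9 FPKM. Neither passed. Among 26 mesenchymal markers no gene passed and 1 had an unadjusted p under 0.05 in the authors' deposited table, with a median of -0.27.

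No gene passed at E11.5 among 19 G1 regulators, 7 primordial germ cell markers, 15 epithelial, hepatic and neural markers, 37 interferon and inflammatory genes, 23 stress genes, 22 glycolysis genes and 5 sex-linked genes. Unadjusted p under 0.05 was listed in the authors' deposited table for 3, 0, 3, 6, 4, 1 and 1 of them. The medians of the epithelial, hepatic and neural list, -0.98 (percentile 0.96), the interferon and inflammatory list, -0.46 (1.38), and the stress list, -0.42 (1.9), lay below the central 95% of random lists. Adjusted over the list alone, 1 G1 regulator rose and 2 fell. Of the 87 changed genes, 29 were listed at 0 in a group, 6 in G1 and 23 in S/G2/M. The smallest p in the authors' deposited table, 5e-05, was shared by 61 genes and had a q of 0.0102. No gene could therefore pass a threshold of 0.01.

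Whether the phase difference itself differed between the ages could not be tested, because that needs values per sample. Among 11818 genes tested at both ages in the authors' deposited tables, Plk1, Top2a and Ube2c rose in S/G2/M at both, against 0.0173 genes for independent calls, and Ncan, a brain proteoglycan gene, fell at both, against 0.178. These numbers for independent calls take every tested gene as equally likely to be called, so the excess is a description and no test. No gene changed in opposite directions. Of the 17 genes risen at E10.5 in this set, 14 were also higher at E11.5, and of the 39 fallen, 34 were also lower.

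**Figure D1:**
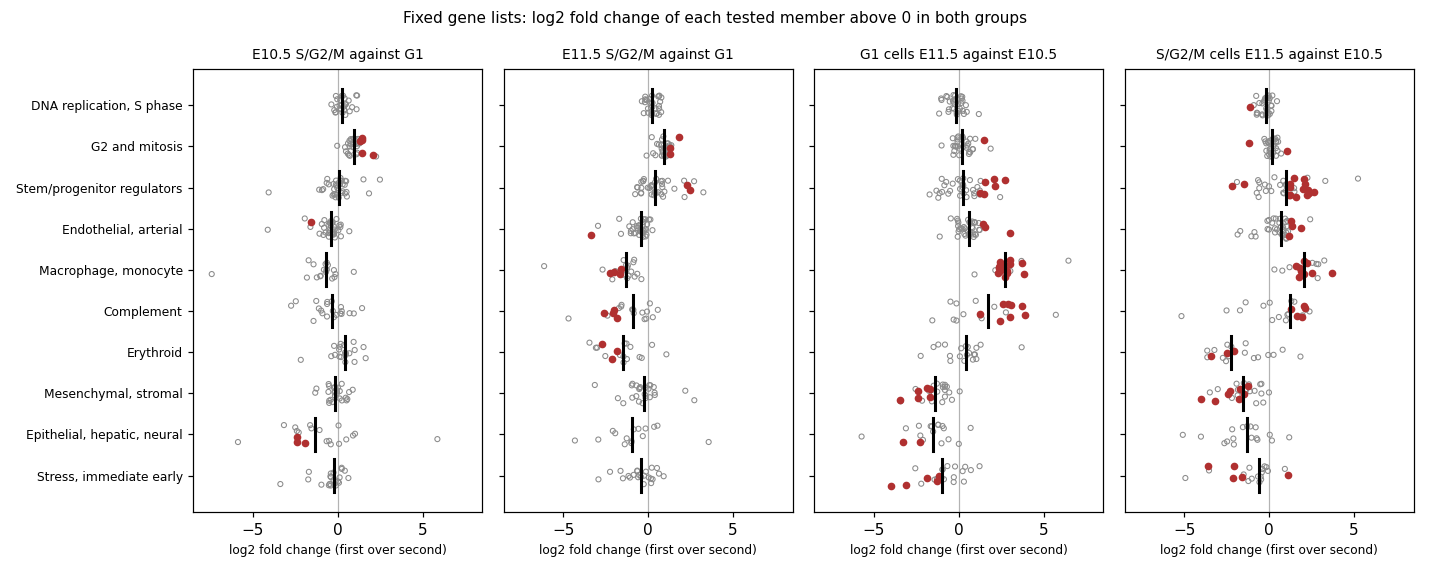
Log2 fold change of each tested member, above 0 in both groups, of 10 gene lists in the 4 comparisons, with the group named first over the group named second. Filled red points passed in the authors' deposited tables, open points did not, and black bars are list medians, such as 0.98 for G2 and mitosis at E10.5 and -1.31 for macrophage markers at E11.5.

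The third comparison set G1 cells at E11.5 against G1 cells at E10.5. With age 14 of 22 macrophage markers, 8 of 22 complement genes, 4 of 10 granulocyte markers and 6 of 36 interferon and inflammatory genes rose, and 6 of 26 mesenchymal markers and 5 of 23 stress and immediate early genes fell. Csf1r, the receptor of macrophage colony-stimulating factor on chromosome 18 (61105572 to 61131139), rose 8.19-fold, from 28.2 to 231 FPKM. Crabp1, which encodes a retinoic acid binding protein and lies on chromosome 9 (54764748 to 54773110), fell 10.9-fold, from 698 to 64.3 FPKM. By the authors' deposited table, 577 of 12953 tested genes changed, with 389 risen and 188 fallen at E11.5.

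Of the 22 tested macrophage markers, 14 rose in G1 cells, and 18 rose when adjusted over the list alone. Adgre1 rose 14.7-fold, from 3.26 to 47.8 FPKM, and Maf rose 8.12-fold. Of the 22 complement genes, 8 rose, over all genes and also adjusted over the list alone. They included C1qa (7.08 and 107.5 FPKM), C1qc (74.2 and 623 FPKM), Itgam (2.92 and 38.7 FPKM) and C3ar1, which rose 6.22-fold, from 14.9 to 93.1 FPKM. Cd93 rose 2.37-fold, and C5ar1 had 6.47 and 44.4 FPKM without passing. The medians of the macrophage and complement lists were 2.74 and 1.72, both above all random lists. Of 10 granulocyte and mast cell markers, 4 rose and 5 rose when adjusted over the list alone, with Csf3r up 11.3-fold and Mpo 6.83-fold. The list median, over the 6 members above 0 in both groups, was 3.13. Of 36 interferon and inflammatory genes, 6 rose, 11 rose when adjusted over the list alone, and the median was 1.60, above all random lists, with Il6ra at 2.38 and 24.3 FPKM and Ifngr1 at 17.2 and 68.0 FPKM.

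Of the 37 tested stem and progenitor regulators, 6 rose in G1 cells. Adjusted over the list alone, 10 rose and 3 fell, and the median was 0.27 (percentile 95.94). Ptprc, which encodes the pan-leukocyte marker CD45, rose 6.65-fold, Spi1 4.43-fold, Ikzf1 4.17-fold and Runx1 2.85-fold, from 9.46 to 27.0 FPKM. Gata2 had 8.01 and 19.6 FPKM and Kit 14.4 and 17.1 FPKM, and neither passed. Among 38 endothelial genes, Lyve1, Pecam1 and Robo4 rose, 3 rose when adjusted over the list alone, and the median was 0.63, above all random lists. Pecam1 had 38.1 FPKM at E10.5 and 113 FPKM at E11.5. The chemokine gene Ppbp was the single megakaryocyte marker of 20 that rose, with 3 risen when adjusted over the list alone and a median of 0.56 (percentile 98.81), and Il2rg was the single lymphoid marker of 14. No erythroid marker of 20 passed, 2 had an unadjusted p under 0.05 in the authors' deposited table, and the median was 0.45 (percentile 97.76).

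Of the 26 mesenchymal and stromal markers, 6 fell in G1 cells, 9 fell when adjusted over the list alone, and 25 were lower, with a median of -1.38, below all random lists. Meox1, a somite transcription factor, fell 11.1-fold, from 31.7 to 2.86 FPKM, Ptn fell 5.25-fold and Prrx1 fell 5.18-fold. Of 19 epithelial, hepatic and neural markers, Emx2 and Tubb3 fell, and 5 fell when adjusted over the list alone (median -1.54). Tubb3 had 129 and 26.7 FPKM. Of 23 stress and immediate early genes, 5 fell and 8 fell when adjusted over the list alone, with a median of -0.96. Fosb fell 15.8-fold, Fos fell 8.49-fold, from 62.4 to 7.35 FPKM, and Egr1 fell 3.66-fold. Lin28a, an RNA-binding protein gene of early embryonic cells, fell 11.1-fold, and Crabp2 fell from 232 to 20.2 FPKM.

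Among the cell cycle lists in G1 cells, none of 31 S-phase genes passed, 4 had an unadjusted p under 0.05 in the authors' deposited table, and Mki67 was the single gene of 32 for G2 and mitosis that rose, from 24.8 to 68.6 FPKM. Among 19 G1 regulators, Gas1 fell 6.62-fold and Cdkn1c 2.74-fold, and 3 fell when adjusted over the list alone. The lactate dehydrogenase gene Ldhb was the single glycolysis gene of 23 that fell, and Ifitm3 was the single primordial germ cell marker of 8 that rose. Xist rose 6.11-fold among 5 sex-linked genes, of which 4 were lower at E11.5 without passing. When adjusted over the list alone, 2 germ cell markers, 1 lymphoid marker, 1 gene of mitosis and 1 sex-linked gene rose and 1 glycolysis gene fell. With a threshold of 0.01 on the q of the authors' deposited table, 301 of the 577 genes were left.

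The last comparison set S/G2/M cells at E11.5 against S/G2/M cells at E10.5. With age 13 of 38 stem and progenitor regulators, 9 of 21 macrophage markers and 5 of 22 complement genes rose, and 8 of 26 mesenchymal markers, 4 of 22 stress and immediate early genes and 3 of 19 erythroid markers fell. Runx1, on chromosome 16 (92601466 to 92826074), rose 4.05-fold, from 10.1 to 40.9 FPKM. Hbb-bh1, an embryonic globin gene on chromosome 7 (103841638 to 103843162), fell 10.9-fold, from 3156 to 289 FPKM. By the authors' deposited table, 520 of 12768 tested genes changed, with 273 risen and 247 fallen at E11.5.

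Of the 38 stem and progenitor regulators, 13 rose and 2 fell in S/G2/M cells. Adjusted over the list alone, 17 rose and 2 fell, and the list median lay above all random lists. Hlf rose 6.11-fold, from 2.88 to 17.6 FPKM, Ikzf1 5.04-fold and Cd47 4.86-fold. Gata2 rose 2.97-fold and Kit rose 2.38-fold, from 12.6 to 30.0 FPKM. The 2 that fell were Hoxa10 and Mllt3. Of 20 megakaryocyte markers, 3 rose and 5 rose when adjusted over the list alone, with Pf4 at 133 and 318 FPKM (list median 0.88). Of 18 lymphoid markers, Flt3, Il2rg and Cd7 rose, and the median over the 14 above 0 in both groups was 1.65. Flt3, a cytokine receptor gene of early lymphoid and myeloid progenitors, had 0.557 FPKM at E10.5 and 6.12 FPKM at E11.5. Of 8 granulocyte and mast cell markers, Mpo, Srgn and Gzmb rose, with Mpo up 8.59-fold to 352 FPKM (list median 2.19). Of 37 endothelial genes, Robo4, Tie1, Pecam1 and Flt1 rose. Adjusted over the list alone, 11 rose and 3 fell, and the median was 0.70.

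Of the 21 tested macrophage markers, 9 rose in S/G2/M cells, 13 rose when adjusted over the list alone, and all 21 were higher (median 2.07). Ctss rose 12.8-fold, from 6.70 to 85.5 FPKM, and Mrc1 rose 5.64-fold. Of 22 complement genes, 5 rose and 6 rose when adjusted over the list alone (median 1.20). They included C1qc, C3ar1, C1qb and Cd93. C3ar1 rose 4.14-fold, from 7.75 to 32.1 FPKM, and Cd93 rose 2.39-fold, while C5ar1 had 6.23 and 13.7 FPKM and did not pass. Of 30 interferon and inflammatory genes, 6 rose and 1, Il1b, fell, and adjusted over the list alone 13 rose and 1 fell (median 1.41). H2-K1 rose 3.83-fold, with the caveat that genes of this family share sequence. Among 10 primordial germ cell markers, Ifitm1 rose 3.76-fold (list median 1.02, percentile 98.43). Xist rose 2.45-fold among 5 sex-linked genes, of which 4 were lower at E11.5 without passing. When adjusted over the list alone, 4 granulocyte, 3 lymphoid and 2 germ cell markers rose and 1 lymphoid marker fell.

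Of 19 erythroid markers, Hbb-bh1, Hba-a2 and Slc4a1 fell in S/G2/M cells. Adjusted over the list alone, 3 fell and 1 rose, and the median was -2.23, below all random lists. Hba-a2 fell 5.51-fold and Slc4a1, which encodes band 3 of the red cell membrane, fell 4.18-fold. Of 26 mesenchymal markers, 8 fell, 13 fell when adjusted over the list alone, and all 26 were lower (median -1.53). Meox1 fell 16.3-fold and Prrx1 5.40-fold. Of 22 stress and immediate early genes, 4 fell and Myc rose, with 5 fallen and 1 risen when adjusted over the list alone and a median of -0.61. Fos fell 12.3-fold, from 59.0 to 4.81 FPKM. None of 17 epithelial, hepatic and neural markers passed, 3 had an unadjusted p under 0.05 in the authors' deposited table, Tubb3 had 25.6 and 15.4 FPKM, and the median was -1.30 (percentile 0.04). Ung was the single S-phase gene of 31 that fell, and the median of that list was -0.17 (percentile 0.9). Among 32 genes for G2 and mitosis Mki67 rose and Ccnb2 fell, and among 19 G1 regulators Cdk6 rose while Gas1 and Ccnd2 fell. Adjusted over the list alone, 2 S-phase genes fell, and the counts of the lists for mitosis and G1 regulators were the same as over all genes. None of 22 glycolysis genes passed, with 6 at an unadjusted p under 0.05 in the authors' deposited table and a list median of -0.29 (percentile 0.13). With a threshold of 0.01 on that table's q, 263 of the 520 genes were left.

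The age differences in the 2 phases were set side by side without a test of their difference. Among 12190 genes tested in both phases in the authors' deposited tables, 137 rose with age in both, against 7.96 for independent calls, and 89 fell in both, against 3.10. The comparisons share no libraries. The joined gene Glul,Mir8114 was the single gene called in opposite directions.

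**Figure D2:**
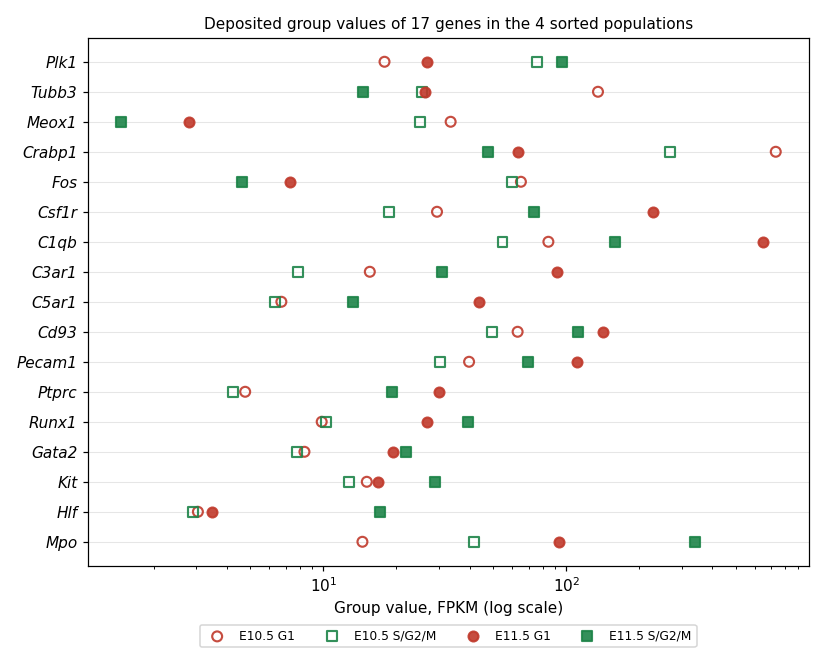
Group values in FPKM, on a log axis, of 17 genes in the 4 sorted populations, taken from the authors' deposited tables of the phases, which were normalized separately for each age. Circles are G1 and squares S/G2/M, open at E10.5 and filled at E11.5, with 1 value per group and no error. C1qb stands at 645 FPKM in E11.5 G1 cells and 158 FPKM in E11.5 S/G2/M cells.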

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

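Leaving out genes listed at 0 in a group was chosen after the data were seen, and the other alternatives were planned. Under a q threshold of 0.01 the changed genes numbered 0 for the phases at E10.5, 0 for the phases at E11.5, 301 for age in G1 and 263 for age in S/G2/M, and 0 genes were called in the phases at both ages, against 4. For the phases these counts of 0 were fixed by the floor of the authors' p-values and do not measure the differences. The smallest p of the authors' test, 5e-05, was shared by 64 genes at E10.5 and 61 at E11.5. Its q was 0.0101 at E10.5 and 0.0102 at E11.5, so no gene could pass 0.01 between the phases. By age the q at this floor was 0.0027 in G1 and 0.0031 in S/G2/M, so the counts at 0.01 cannot be compared with those of the phases. Between the phases, 868 genes at E10.5 and 1027 at E11.5 had an unadjusted p under 0.05 in the authors' test. At E10.5 the phase count of 85 became 49 with at least 5 FPKM in the higher group and 47 without genes listed at 0, since these remove genes. The other totals of changed genes stayed within 1.5 times under every alternative run that could change them, while the 17 genes risen in S/G2/M at E11.5 became 26 at a q threshold of 0.085, 11 with at least 5 FPKM and 11 without genes listed at 0. With a q threshold of 0.01, age in S/G2/M had 128 risen and 135 fallen genes, against 273 and 247, and the cause was not tested. With members of at least 1 FPKM, the median of lymphoid markers at E10.5 changed sign, from 0.10 to -0.08, inside the central 95% of random lists. Of 72 list medians, 44 lay outside the central 95% of random lists, and 45 with members of at least 1 FPKM. Under the latter, 71 kept their side of that range and 1 moved out of it. Median scaling moves all genes of a comparison by 1 constant, so the calls and the places among random lists could not change under it, and it is no check of the normalization. The tables in the other order called 91 genes at E10.5, 83 of them shared, and 80 at E11.5, 76 shared.

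No paired analysis was possible because the deposited columns carry no replicate numbers. For the same reason the replicate block, leaving out each replicate, a fit over 2 groups, no filter on sample values, other normalizations of counts, and other splits of the samples were not run. The depth is unknown, so what it limits could not be assessed.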

Other observations

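The histone group, the macrophage and mesenchymal genes outside the lists and the tests of explanations in this part were chosen only after the results had been seen, and some of the genes tested, neuronal ones among them, had been seen with their values. Replication-dependent histone genes, outside the fixed lists, were mostly higher in S/G2/M cells. Of 57 tested at E10.5, 54 were higher and 7 rose in the authors' deposited table, Hist1h1a, Hist1h1e, Hist1h2ak, Hist1h2be, Hist1h2bf, Hist1h2bl and Hist1h4d, with a group median of 1.25. Hist1h4d had 2189 FPKM in G1 and 6261 FPKM in S/G2/M. At E11.5, 52 of 57 were higher (median 0.84), none passed and 18 had an unadjusted p under 0.05 in the authors' deposited table. These genes share sequence, so values of single members are uncertain.

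In the authors' tables of the phases, normalized separately for each age, Xist had 5.89 FPKM in E10.5 G1, 13.5 in E10.5 S/G2/M, 33.9 in E11.5 G1 and 31.8 FPKM in E11.5 S/G2/M. Of 4 Y-linked genes, in the same order, Ddx3y had 4.06, 4.09, 2.57 and 2.17 FPKM, Kdm5d had 8.92, 4.93, 7.21 and 2.60 FPKM, Eif2s3y had 7.70, 4.90, 4.24 and 3.07 FPKM, and Uty had 3.59, 3.002, 2.87 and 1.71 FPKM. Xist (p of 0.0024) and Kdm5d (0.0358) at E10.5 and Kdm5d at E11.5 (0.04805) had an unadjusted p under 0.05 between the phases in the authors' deposited tables and did not pass. Xist at E10.5 did rise when adjusted over the list alone. Between the ages Xist passed in G1 and in S/G2/M cells, higher at E11.5, and the 4 Y-linked genes were lower at E11.5 without passing. These are the directions that a larger share of female embryos at E11.5 would give. The sex mix itself was not tested, and without values per sample it cannot be told apart from age for these genes. Between the authors' tables of E11.5 phases in either order, 90 of 11889 genes differed by more than 0.3 in log2 FPKM of the G1 group, 89 of them lower in the second table and by up to 2.28, and 43.3% of these carried provisional names against 4.61% of the rest. At E10.5 no gene differed by as much.

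Neuronal transcripts were higher in G1 than in S/G2/M cells at E10.5, with Tubb3 at 135 against 25.6 FPKM and a median of -1.46 for 29 pan-neuronal genes that had not been called. Admixture of all surrounding tissue as the whole cause was argued against, since mesenchymal markers had a median log2 fold change of -0.16 with a lower quartile of -0.48, although macrophage markers (-0.69, 19 of 20 lower) and endothelial genes (-0.40, 32 of 38 lower) were lower too. A difference between the reporter strains stays open, since the same pan-neuronal genes had a median of -1.07 at E11.5, which does not set it apart from the explanations that follow. Neural progenitor genes, also chosen after the results were seen, shifted little. Their median was -0.107 at E10.5 (9 of 14 lower) and -0.113 at E11.5 (6 of 9 lower). The shift thus lay in neuronal genes more than in neural progenitor genes, which does not by itself separate the open explanations. Post-mitotic neurons in the G1 sort, which the CD31 and CD117 gate should remove, stay open and were not tested. In S/G2/M cells 24 of 30 pan-neuronal genes reached 1 FPKM too. A phase difference within the cluster cells themselves also stays open and was not tested.

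Macrophage and complement transcripts were higher in G1 than in S/G2/M cells at E11.5, with Csf1r at 228 against 73.5 FPKM and C1qb at 645 against 158 FPKM. A lower share of cluster cells as the whole cause, which would raise all other cell types alike, was left undecided. Mesenchymal markers shifted less, with a median of -0.27 and a lower quartile of -0.70, against -1.31 for the macrophage list. Erythroid markers (-1.46, 17 of 19 lower), pan-neuronal genes (-1.07) and the epithelial, hepatic and neural list (-0.98, 12 of 15 lower) went with the lower share. Genes of the cluster cells, which a lower share in G1 would make higher in S/G2/M, were divided. Stem and progenitor regulators went with it (0.40, 27 of 38 higher), and endothelial genes went against it (-0.41, 35 of 38 lower). The sort markers were divided too, with Kit at 16.9 and 28.9 FPKM and Pecam1 at 111 and 69.9 FPKM in G1 and S/G2/M. Macrophages in the G1 sort stay open, since 30 macrophage genes outside the list had a median of -1.56 with 29 lower, but the CD117 gate should remove most macrophages and 20 of 23 list markers reached 1 FPKM in S/G2/M cells too. A difference of phase or of reporter strain within cluster cells, which these tests do not separate from macrophages in the sort, stays open and was not tested, nor was the source of the complement transcripts.

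Mesenchymal transcripts were lower at E11.5 than at E10.5 in both phases, with Meox1 at 31.7 and 2.86 FPKM in G1. A lower share of cluster cells at E10.5 as the whole cause, which would raise all other cell types alike, was left undecided in G1. Erythroid markers moved against it, with a median of 0.45 and a lower quartile of -0.50. At E11.5, however, erythroid markers were themselves lower in S/G2/M than in G1 cells (-1.46, 17 of 19 lower). The change of erythroid markers with age therefore decides in neither phase. The epithelial, hepatic and neural list (-1.54, 17 of 19 lower) and pan-neuronal genes (-1.35, 24 of 28 lower) went with the lower share. In S/G2/M macrophage markers, with a median of 2.07, moved against it, but erythroid markers (-2.23, 16 of 19 lower) and the epithelial, hepatic and neural list (-1.30) went with it, pan-neuronal genes were near 0 (-0.13, 16 of 28 lower), and a rise of macrophages with age stays open. Mesenchymal cells in the E10.5 sorts, which the CD31 and CD117 gate should remove, were left undecided, since mesenchymal genes outside the list had medians of -0.51 in G1 (15 of 21 lower) and -0.97 in S/G2/M (18 of 23 lower). Genes of the cluster cells, which a lower share of these cells at E10.5 would make higher at E11.5, mostly went with that share. In G1 these were stem and progenitor regulators (0.27, percentile 95.94, 25 of 37 higher) and endothelial genes (0.63, 30 of 38 higher). Pecam1 rose there and Kit did not pass. In S/G2/M 27 of 38 regulators and 28 of 37 endothelial genes were higher, and Kit and Pecam1 rose. A change with age could raise these genes too, so they do not decide. Age itself, which could change expression in the cluster cells, stays open and was not tested.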
